A study of Mus musculus and Homo sapiens with 11 samples.

How the data were processed

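Polyadenylated RNA of cultured mouse MMTV-ErbB2 mammary tumour cells was sequenced from 3 libraries of the parental line and 3 of its brain metastatic derivative, BrM. The labels name 2 library kits, TruSeq RNA v2 and NEBNext Ultra, without saying which library was made with which, and an Illumina HiSeq sequencer. The media are given as DMEM or RPMI, again not per library. The 5 human HCC1954 libraries of the series were not analysed here. The deposited signal values were normalised read counts made by the authors, whose processing fields name STAR, HTSeq and the builds GRCh38 and GRCm38 with no versions, and do not say which tool gave the scaling. Checked on the table, 100% of the values above 0 in each library were whole multiples of 1 read to within 0.01 read, so the reads were recovered by dividing each library by its value of 1 read. The table listed 24062 genes, 4879 of them at 0 in all 6 libraries. Of the 24062, 27 had symbols turned into dates, 22 of them among the genes tested. They were kept in the counts and named nowhere.

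The comparison was BrM against parental, with the group alone in the model. Genes with a mean value of at least 10 over the 6 libraries were tested, 13821 in all, with limma 3.58.1 under R 4.3.3 on log2 of the value plus 1, moderated with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences of group means on that scale. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Where values are printed for genes named by the rule below with 1 to 3 reads in a group, the ratio of pooled reads is given with an exact 95% interval. Those without a read have a bound from a floor of 3 reads over the group. Genes named after their values were seen have group values or limma folds only.

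The groups, the tests, the 32 gene lists, the rule for named genes and the alternatives named next were chosen before the data were examined. The rule named Erbb2 and the measured genes of the brain metastasis list; the 10 genes that rose most and the 10 that fell most among called genes with a mean of at least 100, no overlap between groups and no predicted or clone symbol; and, for each list, up to 4 called members with the smallest p-values, or the 2 members of highest mean where none was called. Results that need items withheld for evaluation were left out of the text. The alternatives were other pseudocounts, filters, scalings, moderation settings, array weights, a replicate block, a term for numbered libraries, edgeR 4.0.16 with TMM and DESeq2 1.42.0 on recovered reads, and leaving out each library in turn. edgeR called 3753 genes, 3675 of them among the 3881 of limma, and DESeq2 called 5075, 3846 of them shared. Averaging BrM replicates 2 and 3, and centring each chromosome on its median, were added after seeing the data. Splits of the 6 libraries into 3 and 3 number 10, so no share of splits can fall under 0.1.

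Gene positions came from the GENCODE M21 annotation of GRCm38, which matched 98.1% of the listed genes by symbol, 934 of them through an older symbol. The methods were tested on simulated data for BrM against parental with the same 13821 genes. Of 100 genes planted at 2-fold limma recovered 7%, and of 100 planted at 4-fold 75%, with 3 false calls. edgeR recovered 7% and 77% with 3 false calls, and DESeq2 35% and 96% with 54. Far fewer genes were planted than the 28.1% of tested genes called in the data. The adjustment is stricter when few genes change, so these recoveries do not measure the sensitivity of the reported test. Camera found the shifted list in 20 of 20 simulations and called 0 of 600 unchanged lists. Simulated genes were drawn independently of each other, so the 0 of 600 does not cover false calls of lists with correlated members. In the data, estimated correlations of the called lists went from 0.0537 (mesenchymal) to 0.738 (ribosomal proteins). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15 and NumPy 2.4.6.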

Results

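RNA-seq was carried out on cultured cells of a mouse mammary tumour line, MMTV-ErbB2, and of a derivative of that line selected for growth as brain metastases, called BrM. MMTV-ErbB2 tumours arise where the mouse mammary tumour virus promoter drives ErbB2, the receptor tyrosine kinase also known as HER2. The analysed table held 3 libraries of the derivative and 3 of the parental line. A further 5 libraries of the human breast cancer line HCC1954 and its brain metastatic derivative belong to the series and were not analysed here. The growth protocol describes cells in culture at 80% confluence, while the series' design field describes brains of mice that had received human lines. The mouse libraries were read as cultured cells, which the labels do not state library by library. Reads assigned to genes numbered 39304974, 46683735 and 40140819 in parental replicates 1, 2 and 3, and 29877087, 38512988 and 39106969 in BrM replicates 1, 2 and 3. Values below are scaled read counts, given as mean ± SD over n = 3 libraries per group. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

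The comparison asked which genes differ between the brain metastatic derivative and the line it was taken from. The labels assign neither the library kits nor the media to libraries. A difference of kit or medium between the groups therefore cannot be told apart from one of the derivative. Many mesenchymal, matrix and inflammatory genes were lower in the derivative, and epithelial genes went both ways. Vimentin, an intermediate filament of mesenchymal cells, was 16.2-fold lower (2246 ± 399.6 against 37484 ± 12566). Keratin 18, an intermediate filament of simple epithelia, was 2.27-fold higher (43588 ± 4629.9 against 19135 ± 993), and E-cadherin (Cdh1), which joins epithelial cells, was 1.55-fold lower (15921 ± 666 against 24720 ± 1826; chosen after its values were seen). Plau, the urokinase-type plasminogen activator, was 25.7-fold higher (13914 ± 2351 against 598 ± 294). Of 13821 genes tested by limma with trend, 3881 differed at an adjusted p under 0.05, 1691 higher and 2190 lower in the derivative, and 2650 of the 3881 differed at least 2-fold. Groups did not overlap for 6640 genes, or 48.0% of those tested, where chance alone would give 10%. The first principal component separated the groups and held 77.2% of the variance, and the second, with 15.4%, set BrM replicate 1 apart from BrM replicates 2 and 3. The count of changed genes was 6519 without BrM replicate 1, 2191 without BrM replicate 2, 2312 without BrM replicate 3, 2505 without parental replicate 1, 2226 without parental replicate 2 and 2922 without parental replicate 3. It was 2279 with BrM replicates 2 and 3 averaged as 1 sample. This alternative was added because 220 genes were at least 2-fold apart between BrM replicates 2 and 3. Between BrM replicates 1 and 2 there were 3614, and between parental libraries 976 to 1683. For the derivative, calls that appear only without BrM replicate 1 rest on the small spread between BrM replicates 2 and 3. Of 31 gene lists tested by camera with a preset correlation of 0.01, 10 were called, 1 higher and 9 lower. Some lists share members, so these calls are not independent. Splits of the 6 libraries that mixed both groups gave up to 18 called lists by the same test. With an estimated correlation camera called 0, with 1 at an unadjusted p under 0.05. Fry, a test of direction within a list, called 9. Among them were the luminal list, called higher, and the basal and brain cell lists, called lower, none of which camera called. Of 129 passing genes carried through the alternatives, leaving out 1 library moved the fold of 36 by more than 1.5 times and ended the call of 34. Cdh1 lost its call without parental replicate 2, or BrM replicate 2 or 3 (adjusted p 0.0512 to 0.0633).

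**Figure D1:**
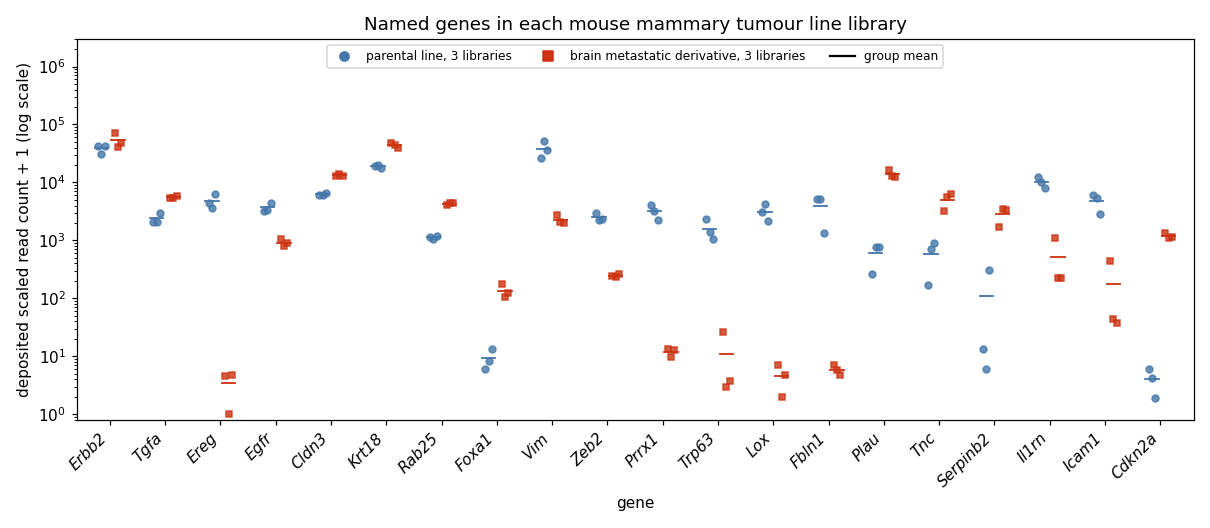
Scaled read count plus 1 on a log axis for 20 named genes in each library, with parental libraries as circles, libraries of the derivative as squares, and lines at group means. Vim, Zeb2, Prrx1, Lox and Fbln1 lie lower in all 3 libraries of the derivative, and Krt18, Rab25, Plau and Cdkn2a lie higher in all 3, with Vim at 37484 in the parental line and 2246 in the derivative.

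The largest differences were close to presence against absence. Among genes with a mean of at least 100 and no overlap between groups, those that rose most were Hgfac, Cdkn2b, Acan, Cdkn2a, Gpa33, Ptplad2, Parvb, Mllt3, Hoxc10 and Cntfr. Cdkn2a and Cdkn2b, which encode cyclin-dependent kinase inhibitors and lie next to each other on chromosome 4 (GRCm38, 89274471 to 89294653 and 89306299 to 89311039), stood at 1185 ± 117 in the derivative and 3.11 ± 2.08 in the parental line for Cdkn2a. For Cdkn2b the values were 2639 ± 683 against 6.24 ± 5.13. Their log2 fold changes were 8.32 (SE 0.46, adjusted p = 0.000154) and 8.84 (SE 0.68, adjusted p = 0.000409). Mllt3 and Ptplad2 lie in the same stretch of chromosome 4, and Ptplad2 overlaps Focad on the other strand; 26 of 148 named genes overlap another tested gene, and the strand setting of the counting is not stated. Acan, which encodes the proteoglycan aggrecan, rested on only 2 reads in the parental libraries and was 876-fold (242 to 7243) higher by the ratio of reads, with an exact 95% interval for counting error alone. Cntfr, the receptor subunit for ciliary neurotrophic factor, had 2 parental reads as well and was 441-fold (122 to 3648) higher. Hgfac, the activator of hepatocyte growth factor, was 475-fold higher (5038 ± 479 against 10.3 ± 4.81). Cdkn2b moved from 458-fold to 269-fold without parental replicate 3.

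Those that fell most were Brinp3, Cyba, Pitx1, Mgp, Robo1, Zfp275, F5, Ctsz, Saa3 and Ereg. Mgp, matrix Gla protein, was at 11.1 ± 8.92 in the derivative and 31729 ± 28808 in the parental line, and the cathepsin gene Ctsz was at 3.21 ± 3.68 in the derivative and 7017 ± 1924 in the parental line. Cyba, a subunit of the phagocyte NADPH oxidase, had 1 read in the derivative and was 23784-fold (4268 to 939439) lower by the ratio of reads. Pitx1, a homeobox transcription factor, and Robo1, an axon guidance receptor, also had 1 read each there and were 17620-fold (3162 to 695997) and 11092-fold (1990.5 to 438153) lower. F5, coagulation factor V, had 3 reads and was 4507-fold (1542 to 21856) lower. Zfp275 had no read in the derivative against 2171 ± 343 in the parental line, which makes it at least 2137-fold lower with a floor of 3 reads over the group. Intervals and floors cover counting error only. For tested genes named by the rule with 1 to 3 reads in a group, limma folds on log2 of the value plus 1 were smaller than the ratio of reads. With more reads this need not hold, as for Ctsz, which was 2038-fold lower by the ratio of reads and 2062-fold by limma. Mgp moved from 2958-fold to 1818-fold without parental replicate 1, 1436-fold without BrM replicate 2 and 4439-fold without BrM replicate 3. Ctsz moved from 2062-fold to 3288-fold without BrM replicate 3.

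Erbb2 itself was high in both groups and did not pass the test, at 53009 ± 15396 in the derivative and 38634 ± 6649 in the parental line (log2 fold change 0.43, SE 0.25, adjusted p = 0.243). Of the 13 tested ErbB receptors and ligands, 4 rose, 3 fell and 6 did not pass (5 higher and 3 lower adjusted over the list alone). The ligand Tgfa rose 2.34-fold (5498 ± 228 against 2387 ± 541). Egfr, the receptor for that ligand, fell 4.02-fold (916 ± 123 against 3705 ± 655), the ligand Nrg2 fell 6.78-fold (203 ± 62.5 against 1341 ± 156), and the ligand epiregulin (Ereg) fell from 4772 ± 1331 to 2.46 ± 2.13. The list did not move as a set by camera (adjusted p = 0.584); its median was 0.43 and its mean -0.67, which differ in sign. Ereg moved from 1660.5-fold to 992-fold without BrM replicate 2.

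Genes that earlier work has linked to brain metastasis did not move one way. Of 22 tested, 3 rose, 7 fell and 12 did not pass (4 higher and 11 lower adjusted over the list alone), and camera gave an adjusted p of 0.485. Tenascin C (Tnc), a matrix glycoprotein, rose 10.1-fold (5013 ± 1582 against 592 ± 380.1, adjusted p = 0.0111). Serpinb2, an inhibitor of plasminogen activators, rose 93.7-fold (2844 ± 1013 against 107 ± 171, adjusted p = 0.0159), and Apoe rose 3.21-fold (234 ± 66.6 against 72.3 ± 23.1, adjusted p = 0.0156). Serpinb2 and Apoe each lost the call in 6 of 23 alternatives, and Tnc in none. Serpinb2 lost its call without parental replicate 1 or 2, or BrM replicate 2 or 3 (adjusted p 0.0505 to 0.0646). Apoe lost its call without parental replicate 2 or 3, or BrM replicate 2 or 3 (adjusted p 0.0527 to 0.0671). Tnc moved from 10.1-fold to 6.05-fold without parental replicate 1. Serpinb2 moved from 93.7-fold to 42.6-fold without parental replicate 2 and 305-fold without parental replicate 3. Parental replicate 3 held Serpinb2 at 304 against 12.2 and 4.94; over the alternatives its log2 fold change went from 4.73 to 8.25 around 6.55. The actin-bundling gene Fscn1 fell 28-fold (209 ± 46.6 against 6072 ± 2216). Gas6 and its receptor Axl both fell, Gas6 16.9-fold (1462 ± 1394 against 19142 ± 5272) and Axl 1.89-fold (16544 ± 1739 against 31255 ± 4105), although Axl remained abundant and lost its call in 1 of 23 alternatives. Angptl4 fell 6.48-fold (144 ± 68.3 against 965 ± 545) and osteopontin (Spp1), among the most abundant transcripts of the parental line, fell 2.48-fold (adjusted p = 0.0327) and lost its call in 7 of 23 alternatives. The protease Ctss and the chemokine receptor Cxcr4 fell from low levels (2.66 ± 3.13 against 31.3 ± 20.3 and 1.94 ± 2.59 against 22.3 ± 20.7). Ctss lost its call in 6 and Cxcr4 in 17 of 22 alternatives. Spp1 lost its call without parental replicate 1 or 3, or BrM replicate 2 or 3 (adjusted p 0.0724 to 0.12). Ctss lost its call without parental replicate 1 or 2, or BrM replicate 2 or 3 (adjusted p 0.084 to 0.118). Cxcr4 lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0628 to 0.144). Gas6 moved from 16.9-fold to 28.3-fold without BrM replicate 1. Ctss moved from 10-fold to 16.2-fold without BrM replicate 1 and 6.08-fold without BrM replicate 2. Cxcr4 moved from 8.04-fold to 4.98-fold without parental replicate 2 and 13-fold without BrM replicate 1. L1cam, a neural adhesion molecule, was at 265 ± 156 in the derivative and 90.9 ± 105 in the parental line and did not pass the test (adjusted p = 0.174). Nor did Ptgs2 (adjusted p = 0.18), Hbegf (adjusted p = 0.857), Serpinb6b (adjusted p = 0.941), Serpinb9 (adjusted p = 0.104), Pcdh7 (adjusted p = 0.0826), Gja1 (adjusted p = 0.869), Lcn2 (adjusted p = 0.0673), Mmp9 (adjusted p = 0.0845), Vegfa (adjusted p = 0.0648), Csf1 (adjusted p = 0.0876) or Csf2 (adjusted p = 0.433). Without BrM replicate 1, Lcn2 (limma adjusted p = 7.26e-05), Vegfa (0.00128), Csf1 (0.00776) and Hbegf (0.0251) passed as lower. Serpinb9 (0.0201) and Mmp9 (0.0337) passed as higher. The derivative then rested on BrM replicates 2 and 3, with 220 genes at least 2-fold apart against 976 to 1683 between parental libraries. Their small spread may be technical, so these values are weak evidence. Lcn2 was at 108384 in BrM replicate 1 against 691 and 624 in BrM replicates 2 and 3, with 152314 to 383422 in the parental line, and Vegfa at 11152 against 1588 and 1603. Over the alternatives the adjusted p went from 9.57e-06 to 0.335 for Lcn2 and from 1.94e-05 to 0.185 for Vegfa. Ptgs2 (0.0172) and L1cam (0.0476) passed without parental replicate 3, and Pcdh7 (0.0420) without parental replicate 2. With chromosomes centred Serpinb9 (0.0247) and Pcdh7 (0.0459) passed. St6galnac5, Serpini1, Serpinb3a and Fabp7 were below the expression filter.

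Mesenchymal genes and transcription factors of the epithelial-mesenchymal transition fell as a set by camera at the preset correlation. Of 18 tested, 0 rose, 13 fell and 5 did not pass (0 higher and 13 lower adjusted over the list alone; median log2 fold change -3.28, camera adjusted p = 4.61e-05; adjusted p = 0.609 with an estimated correlation). The transcription factor Prrx1 fell 264-fold (11 ± 2.05 against 3213 ± 915), Zeb2 fell 10.3-fold (244 ± 11.8 against 2543 ± 402) and Twist2 fell 40.7-fold (7.47 ± 0.852 against 343 ± 29.3). Fibroblast and pericyte markers fell with them, 6 of 9 with none higher (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00189; adjusted p = 0.853 with an estimated correlation). The pericyte receptor Pdgfrb was at 1.56 ± 1.93 in the derivative and 2483 ± 1362 in the parental line, Postn was at 44.6 ± 60.8 in the derivative and 7770.0 ± 4365 in the parental line, and decorin (Dcn) had no read in the derivative and was at least 464-fold lower. The fibroblast and pericyte list shares Pdgfra, Pdgfrb, Thy1 and Fap with the mesenchymal list. With the extracellular matrix list it shares Col1a1, Col1a2, Col3a1, Dcn, Lum, Postn and Loxl1. Its fall is therefore not separate support for theirs. Pdgfrb moved from 1034-fold to 1551-fold without BrM replicate 3. Postn moved from 293-fold to 657-fold without BrM replicate 1 and 178-fold without BrM replicate 3. List medians relative to the parental mean were -2.67 in BrM replicate 1 against -3.48 and -2.87 in the others for mesenchymal genes. Those of the fibroblast and pericyte list were -1.99 in BrM replicate 1 against -3.09 and -3.04 in the others, with -1.11 in parental replicate 3.

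Luminal epithelial genes moved in both directions: of 22 tested, 10 rose, 5 fell and 7 did not pass (11 higher and 5 lower adjusted over the list alone). The small GTPase Rab25 rose 3.81-fold (4315 ± 163 against 1133 ± 76.1), the tight junction gene Cldn3 rose 2.14-fold (13308 ± 476 against 6226 ± 356) and the luminal transcription factor Foxa1 rose 15-fold from a low level (134 ± 36 against 8.26 ± 3.67). Among those that fell, named after their values were seen, Krt19 fell 135-fold (14.8 ± 13.1 against 2131 ± 1477) and the luminal transcription factor Gata3 1.8-fold (2249 ± 188 against 4043 ± 185). The set did not pass (camera adjusted p = 0.0556), and its median of 0.58 and mean of -0.09 differed in sign. It passed as higher in 8 of 25 alternatives. Among these were fry (adjusted p = 0.00177) and camera without parental replicate 2 (adjusted p = 0.0462), without parental replicate 3 (adjusted p = 0.0488) and without BrM replicate 3 (adjusted p = 0.0455). Basal and myoepithelial genes also split, 3 higher and 5 lower of 14 (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.779). Trp63, the transcription factor of basal epithelium, fell 224-fold (10.1 ± 13.4 against 1573 ± 663), Acta2, smooth muscle actin, fell 455-fold (3.2 ± 1.53 against 2013 ± 959) and Krt17 fell 60.1-fold (23.3 ± 23.3 against 1125 ± 367), while Sox10 rose 15.3-fold (732 ± 17.3 against 56.7 ± 37.4). Of 8 milk and alveolar genes, 1 rose, 4 fell and 3 did not pass (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.183). That list was called lower in 2 of 25 alternatives, the block over the numbered libraries (adjusted p = 0.0151) and without parental replicate 3 (0.0194). Btn1a1 rose 6.02-fold (728 ± 300.2 against 119 ± 41.6) and Mfge8 fell 2.66-fold (10728 ± 4239.9 against 27496 ± 4895) and lost its call in 3 of 23 alternatives. Mfge8 lost its call without parental replicate 1 or 2, or BrM replicate 2 (adjusted p 0.0528 to 0.0544). Krt19 moved from 135-fold to 238-fold without parental replicate 3, 214-fold without BrM replicate 1 and 85.5-fold without BrM replicate 2. Trp63 moved from 224-fold to 447-fold without BrM replicate 1 and 148-fold without BrM replicate 2. Krt17 moved from 60.1-fold to 101-fold without BrM replicate 1. Sox10 moved from 15.3-fold to 9.84-fold without parental replicate 3. With chromosomes centred Foxa1 was 7.5-fold higher and Gata3 passed no longer (adjusted p = 0.0532). The basal list had a median of 0.13 in BrM replicate 1 against -0.61 and -0.60 in the others.

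Extracellular matrix genes fell as a set by camera at the preset correlation, with exceptions that rose. Of 40 tested, 6 rose, 24 fell and 10 did not pass (7 higher and 26 lower adjusted over the list alone; median -1.97, camera adjusted p = 0.0015; adjusted p = 0.856 with an estimated correlation). Lysyl oxidase (Lox), which cross-links collagen, was at 3.6 ± 2.58 in the derivative and 3141 ± 1026 in the parental line, Fbln1 at 4.87 ± 1.19 in the derivative and 3896 ± 2220.1 in the parental line and Col6a2 at 4.77 ± 0.887 in the derivative and 1462 ± 1038 in the parental line. Among those that rose were Tnc and others named after their values were seen: Lama3 rose 32.5-fold (10160 ± 3598 against 488 ± 536), Col4a1 4.42-fold, Col4a2 2.08-fold and Lamb1 1.59-fold. Lamb1 lies on chromosome 12, whose genes were higher as a whole, and with chromosomes centred its log2 fold change went from 0.67 to -0.33 (adjusted p = 0.227). Other genes of laminin chains fell, Lama4 25.3-fold, Lamb3 2.38-fold (9169 ± 3632 against 21545 ± 7098) and Lamb2 1.66-fold, as did nidogen (Nid1), a basement membrane protein, 131-fold. Lama5, Lamc1, Hspg2, Col18a1 and Col7a1 did not pass. With chromosomes centred Col4a2 (0.054) and Lamb2 (0.0604) passed no longer and Lamc1 passed (adjusted p = 0.03). The median of the list relative to the parental mean was -1.34 in BrM replicate 1 against -2.55 and -2.53 in the others. Col4a1 lost its call without parental replicate 1 or 2 (adjusted p 0.053 to 0.0533). Col4a2 lost its call without parental replicate 1 or 2, or BrM replicate 2 or 3 (adjusted p 0.0955 to 0.116). Lamb1 lost its call without parental replicate 1, 2 or 3, or BrM replicate 3 (adjusted p 0.055 to 0.0888). Lamb3 lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0533 to 0.109). Lamb2 lost its call without BrM replicate 2 (adjusted p = 0.0528). Fbln1 moved from 569-fold to 894-fold without parental replicate 3. Lama3 moved from 32.5-fold to 17.6-fold without parental replicate 1 and 62.2-fold without parental replicate 3. Lama4 moved from 25.3-fold to 52.3-fold without BrM replicate 1 and 16.7-fold without BrM replicate 2.

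Integrin and adhesion genes fell as a set more weakly, again by camera at the preset correlation only. Of 26 tested, 3 rose, 11 fell and 12 did not pass (4 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.0392; adjusted p = 0.856 with an estimated correlation). The adhesion molecule Alcam fell 8.09-fold (289 ± 8.62 against 2363 ± 369) and syndecan 4 (Sdc4) fell 2.78-fold (7776 ± 272 against 21650 ± 1781), while syndecan 1 (Sdc1) rose 4.57-fold (39261 ± 2134 against 8720.0 ± 1889). Chl1, a close relative of L1cam, fell 9.52-fold from a low level. Proteases and their inhibitors did not move as a set (camera adjusted p = 0.392): of 23, 2 rose, 8 fell and 13 did not pass (2 higher and 8 lower adjusted over the list alone). Plau rose, and the inhibitors Serpine2 and Timp3 fell 85.6-fold (441 ± 589 against 20208 ± 7231) and 9.65-fold (16706 ± 11959 against 143945 ± 51068). Serpinb2, an inhibitor of plasminogen activators outside this list, rose as Plau did (log2 fold change 6.55). The membrane protease Mmp14 fell 2.84-fold (5608 ± 1052 against 15774 ± 164). Targets of TGF-beta and YAP signalling fell, 6 of 20 with none higher (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0227; adjusted p = 0.873 with an estimated correlation). Among them Id1 fell 4.51-fold (1555 ± 183 against 7063 ± 1319), Id3 6.12-fold and Ankrd1 5.44-fold. The adhesion call was lost without BrM replicate 2 (adjusted p = 0.0567) and without parental replicate 3 (adjusted p = 0.13), and the TGF-beta and YAP call without parental replicate 2 (adjusted p = 0.0762). Serpine2 moved from 85.6-fold to 190.4-fold without BrM replicate 1 and 56.2-fold without BrM replicate 3. Sdc1, on chromosome 12, was 2.28-fold higher with chromosomes centred. The fall of the adhesion list lay mostly in BrM replicates 2 and 3, with a median of -0.31 in BrM replicate 1 against -1.06 and -0.95 in the others. For TGF-beta and YAP targets it was -0.48 in BrM replicate 1 against -0.78 and -0.74 in the others, with -0.56 in parental replicate 1.

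**Figure D2:**
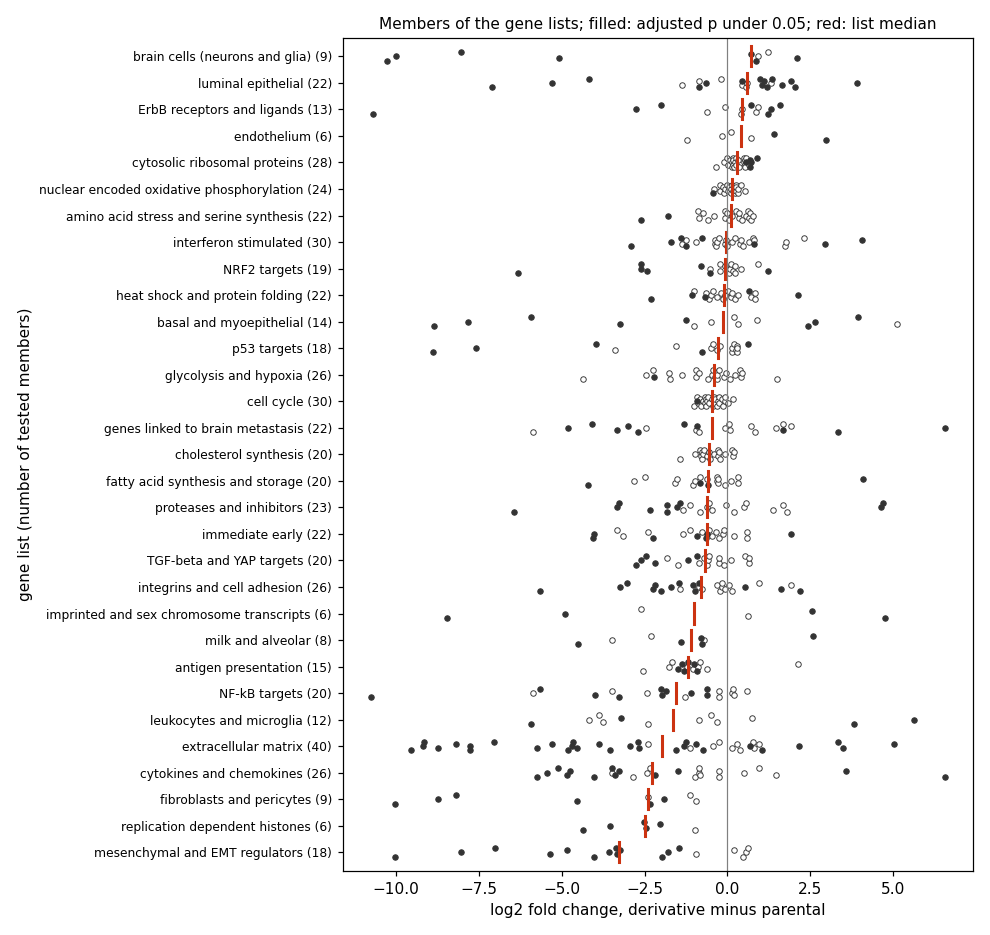
Log2 fold change, derivative minus parental, of each tested member of 31 gene lists, ordered by list median (red bars); filled points have an adjusted p under 0.05 and open points do not. The lowest median is that of the mesenchymal list at -3.28, and members of most lists spread to both sides of 0.

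Inflammatory genes were lower in the derivative. Of 26 cytokines and chemokines, 2 rose, 11 fell and 13 did not pass (2 higher and 15 lower adjusted over the list alone; median -2.26, camera adjusted p = 0.00453; adjusted p = 0.873 with an estimated correlation). Ccl5 fell 11.1-fold (54.3 ± 13.2 against 607 ± 100.1), Ccl9 10.6-fold (119 ± 83.9 against 1099.9 ± 103) and the interleukin 1 receptor antagonist Il1rn 26.7-fold (511 ± 499 against 10309 ± 2267), and Il6, with 1 read in the derivative, was 253-fold (45 to 10017) lower by the ratio of reads. The 2 that rose, named after their values were seen, were the interleukins Il1a (4924 ± 7084 against 29.7 ± 28.2) and Il1b (31.7 ± 43.4 against 0.629 ± 1.09). BrM replicate 1 carried these means, with Il1a at 13104 against 861 and 808 and Il1b at 81.8 against 7.65 and 5.59 in BrM replicates 2 and 3. Il1b lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0551 to 0.148). Il1a moved from 93.4-fold to 57.3-fold without parental replicate 2, 156-fold without parental replicate 3, 37.3-fold without BrM replicate 1, 146-fold without BrM replicate 2 and 150.2-fold without BrM replicate 3. Il1b moved by limma from 11.8-fold to 5.3-fold without BrM replicate 1 and 18.8-fold without BrM replicate 3. Its parental mean of 0.629 rests on very few reads, so these folds are understated on the scale of log2 of the value plus 1. Il1rn moved from 26.7-fold to 45.2-fold without BrM replicate 1. Il6 moved by limma from 53.9-fold to 34.3-fold without parental replicate 3. Of 20 NF-kB targets, 10 fell and none rose (0 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.00263; adjusted p = 0.856 with an estimated correlation), among them Birc3 (3.94-fold), Bcl3 (3.61-fold), Saa3 and Icam1 (174 ± 232 against 4743 ± 1636). Saa3 lies in a family of closely similar serum amyloid genes that can share reads. BrM replicate 1 lay closer to the parental line than the other libraries of the derivative in both lists, with a median of -1.02 on the log2 scale relative to the parental mean for cytokines against -2.78 and -2.72, and -0.96 for NF-kB targets against -1.96 and -1.96. Icam1 moved from 49.9-fold to 110.3-fold without BrM replicate 1 and 32.4-fold without BrM replicate 3.

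Antigen presentation genes fell, 6 of 15 with none higher (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.00493; adjusted p = 0.873 with an estimated correlation). Tapbp, which loads peptides onto class I molecules, fell 2.29-fold (6305 ± 826 against 14383 ± 873), the peptide-trimming protease Erap1 fell 2.82-fold (not past in 1 of 23 alternatives), and H2-T23 and H2-Q4, class I genes with closely similar relatives that can share reads, fell 2.48-fold and 2.58-fold and each lost its call in 6 of 23 alternatives. Parental replicate 3 and BrM replicate 1 met in this list, at -0.62 and -0.59, with -1.29 and -1.31 in BrM replicates 2 and 3. Interferon-stimulated genes did not move as a set (camera adjusted p = 0.815): of 30, 3 rose, 5 fell and 22 did not pass (3 higher and 4 lower adjusted over the list alone). Oas3 rose 16.7-fold (1119.7 ± 1039 against 53.1 ± 19.7), Oasl1 7.74-fold (1204 ± 681 against 153 ± 73.3) and Ddx58 1.74-fold, while Parp14 fell 1.71-fold. Ddx58 lost its call in 1 and Parp14 in 4 of 23 alternatives. Erap1 lost its call without parental replicate 2 (adjusted p = 0.0544). H2-T23 and H2-Q4 lost their calls without parental replicate 1 or 2, or BrM replicate 2 or 3 (adjusted p 0.0781 to 0.0907). Parp14 lost its call without parental replicate 1 or 2, or BrM replicate 2 (adjusted p 0.0527 to 0.0618). Oas3 moved from 16.7-fold to 10.1-fold without BrM replicate 1. The list's median was 0.79 in BrM replicate 1 and -0.40 and -0.38 in BrM replicates 2 and 3. Its median (-0.03) and mean (0.13) over all libraries differed in sign.

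Camera at the settings used throughout called none of the proliferation and metabolic lists, although some alternatives did. Of 30 cell cycle genes only E2f1 passed, lower in the derivative (1368 ± 49.2 against 2612 ± 308; not past in 1 of 23 alternatives), with 1 adjusted over the list alone (camera adjusted p = 0.219). Limma called 0 of 20 cholesterol synthesis genes over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2 (camera adjusted p = 0.347); Srebf2, a transcription factor of sterol synthesis, was at 7073 ± 3220.5 in the derivative and 11091 ± 242 in the parental line and passed without BrM replicate 1 (adjusted p = 0.0394). BrM replicate 1 stood far below the other libraries in both lists, at -1.66 against 0.16 and 0.22 for cell cycle and -1.82 against 0.19 and 0.18 for cholesterol synthesis. The cell cycle list was called lower in 5 and the cholesterol list in 4 of 25 alternatives. These were, for both, the replicate block over the numbered libraries (adjusted p = 0.00156 and 0.00915), without BrM replicate 2 (0.0155 and 0.0477), without BrM replicate 3 (0.0176 and 0.0432) and with these averaged (0.0165 and 0.0436). For the cell cycle list the block over all 6 libraries was the other (0.0390). Of 20 genes of fatty acid synthesis and storage, 1 rose, 3 fell and 16 did not pass (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.183). Fads3 rose 17-fold (1130.3 ± 56.7 against 66.3 ± 12.5), and Fabp4, Elovl5 and Me1 fell 18.3-fold, 1.76-fold and 1.49-fold. Me1 lost its call in 14 of 23 alternatives, Fabp4 in 4 and Elovl5 in 3. Me1 lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0711 to 0.129). Fabp4 lost its call without parental replicate 2, or BrM replicate 2 or 3 (adjusted p 0.0579 to 0.062). Elovl5 lost its call without parental replicate 1 or 2 (adjusted p 0.0642 to 0.0804). Fabp4 moved from 18.3-fold to 8.44-fold without parental replicate 1 and 32.9-fold without parental replicate 3. The list was called lower in 1 of 25 alternatives, the block over the numbered libraries (adjusted p = 0.0204). 1 gene fell in each of the glycolysis and hypoxia list (Pfkp, 4.6-fold) and the nuclear oxidative phosphorylation list (Sdha, 1.35-fold), with 0 in each adjusted over the list alone, 5 in each at an unadjusted p under 0.05, 2 and 1 called by edgeR and 5 and 4 by DESeq2 (camera adjusted p = 0.373 for each). Pfkp lost its call in 6 and Sdha in 11 of 23 alternatives. Pfkp lost its call without parental replicate 1 or 2, or BrM replicate 2 or 3 (adjusted p 0.086 to 0.102). Sdha lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0655 to 0.0954). The glycolysis and hypoxia list was called lower in 3 of 25 alternatives, with array weights (adjusted p = 0.00409), the block over the numbered libraries (0.00836) and without parental replicate 3 (0.00859). Its median was 0.24 in BrM replicate 1 against -0.62 and -0.74 in the others, with -0.87 in parental replicate 3; that of the fatty acid list was -1.15 in BrM replicate 1 against -0.40 and -0.45 in the others.

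Camera at the settings used throughout called none of the stress lists, but the immediate early list was called lower in 7 of 25 alternatives, most of them on all 6 libraries, with an adjusted p from 0.00219 to 0.873 and 0.00827 without parental replicate 3. The p53 targets were called lower in 2 of 25, with array weights (adjusted p = 0.0425) and without BrM replicate 1 (adjusted p = 0.0448). Of 22 amino acid stress genes, 0 rose, 2 fell and 20 did not pass, namely Cebpb (3.47-fold) and the cystine transporter Slc7a11 (6.11-fold, not past in 4 of 23 alternatives; 0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.927); the median (0.10) and mean (-0.11) differed in sign. Of 19 NRF2 targets, 1 rose, 6 fell and 12 did not pass (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.503). Nqo1 was at 4.12 ± 3.96 in the derivative and 347 ± 135 in the parental line, Gsta4 fell 6.1-fold and Akr1b8 rose 2.34-fold. Of 18 p53 targets, 1 rose, 4 fell and 13 did not pass (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.426), with the pro-apoptotic gene Pmaip1, at 1 read in the derivative, 1762-fold (316 to 69621) lower by the ratio of reads and Eda2r at 8.35 ± 12.9 in the derivative and 808 ± 201 in the parental line. Of 22 heat shock and folding genes, 2 rose, 3 fell and 17 did not pass (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.901); Hsp90aa1 rose 4.36-fold (84839 ± 25021 against 19068 ± 3975) and Herpud1 fell 4.98-fold. Of 22 immediate early genes, 1 rose, 6 fell and 15 did not pass (2 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.101), with the phosphatase gene Dusp5 3.76-fold higher and Dusp1, which lost its call in 5 of 23 alternatives, 16.6-fold lower. Hsp90aa1, on chromosome 12, was 2.18-fold higher with chromosomes centred. The p53 list had a median of 0.19 in BrM replicate 1 against -0.59 and -0.57 in the others. Slc7a11 lost its call without parental replicate 2, or BrM replicate 2 or 3 (adjusted p 0.0554 to 0.0739). Dusp1 lost its call without parental replicate 1 or 2, or BrM replicate 2 or 3 (adjusted p 0.0511 to 0.0678). Slc7a11 moved from 6.11-fold to 3.82-fold without parental replicate 1 and 9.24-fold without parental replicate 3. Nqo1 moved from 79.1-fold to 120.0-fold without BrM replicate 1. Eda2r moved from 193-fold to 467-fold without BrM replicate 1 and 95-fold without BrM replicate 2. Dusp1 moved from 16.6-fold to 31.3-fold without BrM replicate 1.

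Markers of the other cell types that a tumour or a brain could hold went both ways. Of 9 tested genes of neurons and glia, 3 rose, 4 fell and 2 did not pass (5 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.815; median 0.70 and mean -3.06, which differ in sign). The glutamate transporter Slc1a3, abundant in astrocytes, had 1 read in the derivative and was 5164-fold (927 to 204015) lower by the ratio of reads. Aldh1l1, with 3 reads, was 1858-fold (635 to 9012) lower, and S100b was at 2.28 ± 2.06 in the derivative and 1043 ± 783 in the parental line. The 3 that rose, named after their values were seen, were the astrocyte filament gene Gfap (106 ± 29.9 against 23.4 ± 5.08), the neuronal Map2 (1988 ± 100.5 against 1241 ± 259) and the myelin gene Mbp (2085 ± 27.3 against 1154 ± 177). Of 12 leukocyte and microglia genes, 2 rose, 2 fell and 8 did not pass (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.426): Csf1r (268 ± 45.7 against 7.52 ± 9.84) and P2ry12 (97 ± 71.6 against 5.18 ± 2.26) rose, and Cd14 and S100a8 fell. S100a8 lost its call in 7 of 23 alternatives. S100a8 lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0639 to 0.0947). Map2 lost its call without parental replicate 1 or 3, or BrM replicate 2 or 3 (adjusted p 0.0657 to 0.113). With chromosomes centred Map2 passed no longer (adjusted p = 0.0606). The leukocyte and microglia list had a median of -0.17 in BrM replicate 1 against -2.47 and -1.99 in the others. S100b moved from 262-fold to 172-fold without parental replicate 1 and 489-fold without parental replicate 3. Csf1r moved from 49.1-fold to 93.9-fold without parental replicate 3. Aldh1l1 moved by limma from 1018-fold to 1701-fold without BrM replicate 1. Of 6 endothelial genes, 2 rose, 0 fell and 4 did not pass, Egfl7 and Plvap being the higher ones (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.347). Plvap lost its call in 12 of 22 alternatives. Plvap lost its call without any 1 library other than BrM replicate 1 (adjusted p 0.0647 to 0.124). The endothelial list had a median of 1.28 in BrM replicate 1 against -0.07 and 0.30 in the others. Csf1r, P2ry12, Egfl7 and Plvap each overlap another tested gene on the other strand. Their counts may hold reads of that gene, as the strand setting is not stated.

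Cytosolic ribosomal protein genes were the one list called higher, by a small margin. Of 28, 5 rose and none fell, with 0 adjusted over the list alone by limma, 12 at an unadjusted p under 0.05, 5 called by edgeR and 11 by DESeq2 (median 0.28, camera adjusted p = 0.00384; adjusted p = 0.873 with an estimated correlation). Rplp0 rose 1.59-fold (98418 ± 9359 against 62091 ± 8218) and Rpl5 1.84-fold. They lost their calls in 8 and 9 of 23 alternatives. Rplp0 and Rpl5 lost their calls without any 1 library other than BrM replicate 1 (adjusted p 0.0538 to 0.135). The list median was 0.39 in BrM replicate 1 against 0.40 and 0.22 in the others, and 0.20 in parental replicate 2. Such genes have many processed pseudogenes, so their counts are uncertain. Replication-dependent histone genes fell, 5 of 6 tested (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0104; adjusted p = 0.856 with an estimated correlation). Their messages mostly lack poly(A) tails, which the library type selects, and closely similar copies can share reads; Hist1h2bc was at 133 ± 101 in the derivative and 619.6 ± 102 in the parental line and lost its call in 3 of 23 alternatives. Hist1h2bc lost its call without parental replicate 1 or 2, or BrM replicate 2 (adjusted p 0.0513 to 0.0579). Medians of the histone list were -1.58 in BrM replicate 1 against -2.69 and -3.20 in the others. Of 6 imprinted and sex chromosome transcripts, 2 rose, 2 fell and 2 did not pass (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.834). Grb10, with 3 reads in the derivative, was 679-fold (232 to 3296) lower by the ratio of reads, Igf2 fell 30-fold and Mest rose 5.81-fold; the median and the mean (-1.34) were negative while camera placed the list higher. None of 13 mitochondrially encoded genes was listed in the table. Igf2 moved from 30-fold to 56.8-fold without BrM replicate 1 and 18.4-fold without BrM replicate 3.

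Differences between the groups also followed chromosomes, a description chosen after the data were seen. The 475 tested genes of chromosome 12 had a median log2 fold change of 0.99, a 1.98-fold higher level in the derivative, and 86.3% of them were higher. Their median relative to the parental mean was 0.96, 1.01 and 1.03 in BrM replicates 1, 2 and 3. Foxa1, Sdc1, Hsp90aa1 and Lamb1 lie on this chromosome. Centred on its median, the first 3 were 7.5-fold, 2.28-fold and 2.18-fold higher in place of 15-fold, 4.57-fold and 4.36-fold (adjusted p = 0.00496, 0.00586 and 0.0291), and Lamb1 reversed, from a log2 fold change of 0.67 to -0.33 (adjusted p = 0.227). Chromosomes 2, 14, 7, 13, 3, 9 and 17 had medians of -0.42, -0.38, -0.33, -0.32, -0.31, -0.29 and -0.29, and each of the remaining chromosomes lay between -0.00205 (X) and 0.24 (chromosome 5). With each chromosome centred on its own median, 3097 genes passed, 2779 of them among the 3881.

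**Figure D3:**
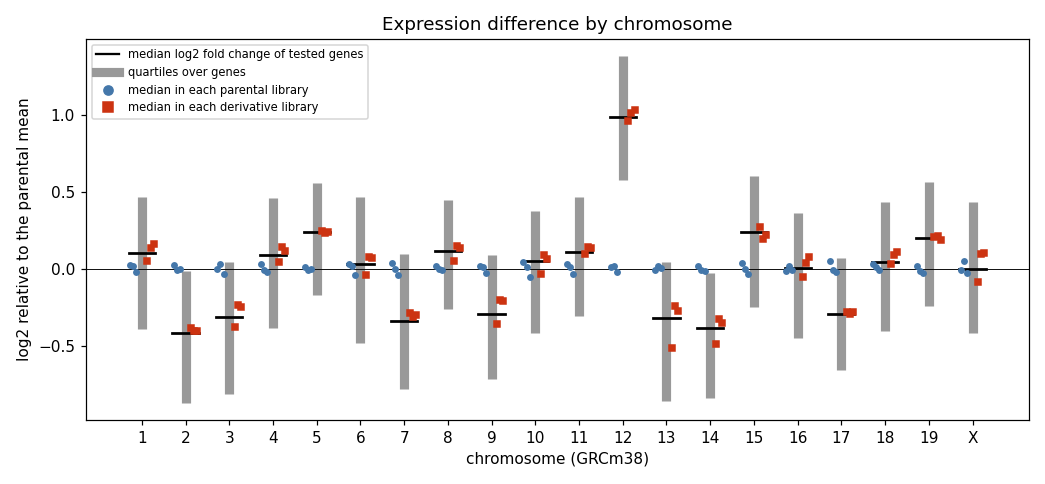
Median log2 fold change of the tested genes of each chromosome (black bars, grey quartiles over genes), with each library's median relative to the parental mean (circles parental, squares derivative). All 3 libraries of the derivative stand near 1 on chromosome 12, at 0.96, 1.01 and 1.03.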

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

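Averaging BrM replicates 2 and 3 and centring chromosomes were tests chosen after the result was seen. Of 144 named genes carried through the alternatives, 129 passed the threshold; 91 of these passed with the same sign under each alternative run, and all 129 kept their sign. The 3881 changed genes (1691 higher, 2190 lower) became 8485 (3949 and 4536) with array weights, 2279 (949 and 1330) with BrM replicates 2 and 3 averaged, and 2029 (729 and 1300) with a replicate block over the numbered libraries only, where fewer samples enter. The replicate block over all 6 libraries gave 4040; correlations between libraries of the same number were 0.30, -0.09 and 0.33, so the numbers were not shown to pair cultures. Leaving out 1 library gave 2191 to 6519 changed genes, 918 to 2911 higher and 1263 to 3608 lower, and the highest value of each came without BrM replicate 1. The 10 called lists became 0 with an estimated correlation. The share of variance on the first component, 77.2%, was 88.8% on the 1000 genes of largest variance, 69.8% without a filter, 74.9% with a pseudocount of 8 and 75.3% to 89.8% with 1 library left out. Apart from the settings with fewer samples or other genes, the cause was not tested. Quantile normalization shifted the median of all genes by 0.136 on the log2 scale, and 56.0% of its calls were higher against 43.6%. Integrin and adhesion genes passed no longer with a mean of at least 50 (adjusted p = 0.0711), the numbered block (0.0911), without parental replicate 3 (0.130), without BrM replicate 2 (0.0567), with centred chromosomes (0.0563) and with an estimated correlation (0.856). TGF-beta and YAP targets passed no longer with the numbered block (0.0513), without parental replicate 2 (0.0762) and by fry (0.0955), ribosomal protein genes with array weights (0.0857) and by fry (0.213), and antigen presentation genes (0.0734) and cytokines (0.0520) by fry. Fry called the luminal list higher (0.00177) and the brain cell (0.0149) and basal and myoepithelial (0.0239) lists lower, none of which camera called. Of the 15 such named genes that did not pass, 10 passed with 1 library left out. Of the tested genes, 64 had no read in the derivative and 8 none in the parental line, which at this depth means not detected, not absent.

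Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 split) gave as many changed, higher, lower or 2-fold changed genes, with 3881, 1691, 2190 and 2650 against 0 as the highest other. For lists 6 splits, the real one included, gave as many as its 10, and the highest other gave 18. The count of lists called by camera at the preset correlation therefore does not set the real grouping apart from mixed ones. Each other split mixed libraries of both groups, so the group difference entered its spread and a low count of genes followed. The counts of 0 therefore do not speak against chance, and the splits are too few for a share under 0.05.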

Other observations

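All tests of this part were chosen after the result was seen, except those on GC content and gene length. Homeobox genes of the A and C clusters, transcription factors that mark position along the body axis, were higher in the derivative: of 9 tested Hoxa genes 8 were called higher, and of 6 tested Hoxc genes 6; the 4 tested Hoxb genes did not pass. Hoxa7 was at 236 ± 9.76 in the derivative and 0.549 ± 0.951 in the parental line (adjusted p = 0.000249), Hoxc9 at 243 ± 5.41 in the derivative and 12.6 ± 8.02 in the parental line (adjusted p = 0.00146) and Hoxb4 at 462 ± 93.7 in the derivative and 606 ± 8 in the parental line (adjusted p = 0.178). Hoxb3 and Hoxb4 passed without BrM replicate 1 (adjusted p = 0.00747 and 0.0226). Some Hox genes overlap, as Hoxc10 and Hoxc5 do, so reads of a cluster are not independent.

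BrM replicate 1 held several genes at levels far from BrM replicates 2 and 3. Nos2, the inducible nitric oxide synthase, was at 10826 in replicate 1 and at 4.78 and 4.66 in replicates 2 and 3, with 6129, 10542 and 6606 in the parental libraries. Lactoferrin (Ltf) was at 130970 in replicate 1 and at 2480.1 and 2316 in the others. Genes of sterol synthesis and the cell cycle were lower there, with Cyp51 at 768 against 10404 and 9972 and Ccna2 at 896 against 5970.3 and 5783. In parental replicates 1, 2 and 3 Ltf was at 56992, 39111 and 40008 and Cyp51 at 7310, 8123 and 7511. Nos2, Ltf and Cyp51 did not pass with all 6 libraries. Without replicate 1, Nos2 and Ltf passed as lower in the derivative (limma adjusted p = 3.09e-05 and 5.56e-05) and Cyp51 as higher (0.0166). The derivative then rested on BrM replicates 2 and 3, which lay close to each other.

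Chromosome 12 genes were higher in the derivative as a whole, with a median 1.06 above that of the other genes on the log2 scale. A trend with GC content or gene length is argued against, since the difference was 1.07 after its removal (bootstrap 1.02 to 1.13), and so is a change in 1 part of the chromosome, since its lowest window median was 0.807. Extra copies of chromosome 12 in the derivative cannot be told apart from other changes of the whole chromosome: the lowest of the 3 library medians, 0.957, restates the pattern, and RNA does not measure copies.

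A run of 8 neighbouring tested genes of chromosome 4, from Mllt3 to Cdkn2b (87769925 to 89311039), was near absent from the parental libraries and expressed in the derivative. Chance placing is argued against, since 0% of 10000 random gene orders held a run as long and the longest held 3. Loss of the segment in the parental line cannot be told apart from silencing, which was not tested: the highest level in any parental library, 1.18% of the derivative's mean among 7 genes with a mean of at least 100, follows from how the run was chosen. RNA or reads of the derivative carried over at 1 share are argued against as the source of all remaining reads. With each library of the derivative in turn as source, the segment kept at least 3.15 times (2.21 to 4.64) the share of Hgfac, the lowest other gene. Pooled over libraries the shares were 0.719% and 0.203%. Mtap (0.976%) and Klhl9 (1.04%) held 276 and 68 of the segment's 429 parental reads. For Cdkn2a (0.262%) and Cdkn2b (0.237%) such carry-over stays open. A comparison with the median of the 20 lowest other genes, 0.298, decides nothing, as no run chosen this way can reach its bound.

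BrM replicate 1 stood apart from BrM replicates 2 and 3, with 3582 genes at least 2-fold from their mean. Admixture of parental cells is argued against as the whole cause, since 63.1% of the genes at least 4-fold higher in replicate 1 than in both others lay above all 3 parental libraries. A small admixture stays open. Over 58 genes high in the parental line, the median share of the parental mean was 1.19% in replicate 1 against 0.231% and 0.255%. These genes were chosen as low in replicates 2 and 3, so the contrast decides nothing. A mislabelled library of a line without the shift of chromosome 12 is argued against, since that median differed by at most 0.0758 between replicate 1 and the others. Another line that shares the shift would give the same value and stays open. Medians of chromosome 13 lay further apart, at -0.51 in replicate 1 against -0.24 and -0.27. Those of chromosome 2 were close, at -0.39 against -0.40 and -0.40. A trend with GC content or gene length is argued against by the 87.4% of genes that remained 2-fold apart after its removal. Differences in kit, medium or culture state may remain, which the labels do not assign to libraries. No biological explanation was tested.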
